A study of Homo sapiens with 63 samples.

How the data were processed

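The data were bulk RNA sequencing of bead-isolated CD14 positive monocytes from 63 donors. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a stranded poly(A) kit. Reads were paired and came from an Illumina NextSeq instrument, and were aligned to hg38 and counted per gene, per the series' design text. Per the submitters' processing notes the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.9a, featureCounts, Subread 2.0.1 and DESeq2 1.32.0. The annotation release and the strand setting of the counting were not given in the sources used here, so values of antisense and overlapping genes are uncertain. The deposited table held raw counts made by the authors, 1 whole number per gene and library, per Ensembl gene identifier. Every gene in it had at least 10 counts in at least 16 libraries. It held 0 mitochondrially encoded genes, so the share of mitochondrial reads was not used here. Gene names were matched by identifier to GENCODE version 44, which named 19087 genes, and coordinates are those of that annotation on GRCh38. Of the genes, 13261 were protein coding and 3091 were long noncoding. Donor age, a covariate in the submitters' fit per the series' design text, was not used here, nor was any clinical detail. P-values assume that each library came from a separate donor, as per the labels. Reads of close paralogs such as HBA1 and HBA2 can be assigned to either or dropped, so values of such genes are uncertain.

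Groups came from the library titles. The set, B1 or B2, came from a tag in the library names whose meaning the labels do not state. It was treated as a possible batch, and each group was in both sets. 12 genes whose level follows sex were left out of every test. The 10 most abundant genes took between 4.7 and 8.0% of the counts of a library. Total counts of 26573114 to 42547411 leave counting error small beside the spread between donors for all but the least abundant genes, and intervals cover the number of libraries only.

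Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Scores were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots with matplotlib 3.10.9. Genes passed filterByExpr with a minimum count of 10, which removed 44 genes and left 19066, and libraries were scaled by TMM. All 63 libraries entered 1 quasi-likelihood fit with a term for each of the 3 groups and a covariate for set. The SSc comparison took the equal-weight mean of lcSSc and dcSSc against HC. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. A further fit held the interaction of disease with set. The SE of a log2 fold change was its size divided by the root of the F statistic. Log2 CPM used a prior count of 2.

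The gene lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. There were 31 lists. They covered type I interferon, interferon gamma, Notch, NF-kB inflammatory mediators, immediate early genes, heat shock, MHC class II, classical and non-classical monocytes, T, B and NK cells, neutrophils, platelets, red cells, dendritic cells, and eosinophils and basophils. The others were profibrotic mediators, alternatively activated macrophages, glucocorticoid response, coagulation, cholesterol and lipids, adhesion and chemotaxis, complement, Toll-like receptors, glycolysis and hypoxia, oxidative stress, cell cycle, ribosomal proteins, the nuclear respiratory chain and mitochondrially encoded genes. The last had no gene in the table, which left 30. The red cell list kept 6 of its 14 genes. Lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. List scores were the mean log2 CPM over the list's genes in a library. Pearson and Spearman correlations had two-sided permutation p-values. Scores were compared by two-sided permutation of the group labels within set, with 100000 permutations, or by exact enumeration within 1 set. Permutation p-values of the 30 lists were adjusted together by Benjamini-Hochberg. Where genes are said to be adjusted over the list alone, Benjamini-Hochberg was applied to the genes of that list only. The plan held permutation tests of scores for the interferon and Notch lists only, between SSc and HC and for their correlation in SSc. Permutation tests of other list scores and of scores by subtype were not in that plan. Neither were the adjustments over the 30 list scores and over a list alone. The share of SSc libraries above the HC range has an exact binomial 95% interval.

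The rule for named genes took, per comparison, genes with a mean log2 CPM of at least 1 and a symbol that does not mark a clone or an unnamed locus. It took the 10 called genes with the smallest p in each direction, or the 3 with the smallest p where none was called. It added up to 4 called members per list, the 4 genes with the smallest p in the interferon and Notch lists, and the 2 most abundant genes of each other cell type, given here for SSc against HC only. HDC, the other basophil gene taken by the rule, had a log2 fold change of 0.64 ± 0.56 (SE) between SSc and HC. Genes of the glucocorticoid, macrophage and red cell lists beyond these, and genes called only by another tool, were named after their values were seen. A gene that the rule took is not reported here.

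A library stood apart when its median Spearman correlation with the libraries of its set was more than 4 scaled median absolute deviations below the set's median. This marked 4 libraries: 1 HC, 2 lcSSc and 1 dcSSc, with correlations down to 0.899 against a median of 0.967. Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no filter on counts, no libraries standing apart, marker levels of 6 other cell types as covariates, no set covariate and each set alone. For scores, z values per gene and a prior count of 0.5 were also tried. A fit with the 2 subtypes as 1 group was planned as well. Leaving out each library in turn was chosen after seeing the data. Group labels were also permuted within set to give 50 splits, the real one included.

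The computation was tested on simulated data: counts were drawn from the real means, dispersions and library sizes, with known changes put into a random set of genes, and 18906 genes passed the filter. For SSc against HC, 61.2% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 7 false calls. Each gene was drawn independently, without the structure shared between real libraries, so these values do not give the power or false calls in the real data. Camera and fry both called the shifted interferon list and 0 of the 29 others, in a simulation without correlation between genes.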

Results

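Gene expression was measured in monocytes, the circulating phagocytes that carry the lipopolysaccharide co-receptor CD14, which were isolated from peripheral blood with anti-CD14 magnetic beads. Bulk RNA sequencing gave 1 library per donor, per the labels. The donors were 48 people with systemic sclerosis (SSc), an autoimmune disease of skin and organ fibrosis with damaged small vessels, and 15 healthy controls (HC). Of the SSc libraries, 30 came from limited cutaneous disease (lcSSc) and 18 from diffuse cutaneous disease (dcSSc), in which skin thickening is more widespread. A tag in the library names split them into a set B1, with 7 HC, 16 lcSSc and 8 dcSSc libraries, and a set B2, with 8 HC, 14 lcSSc and 10 dcSSc libraries. The total count per library ranged from 26573114 to 42547411, with a median of 31334107. It ranged from 27651880 to 33964159 in HC, from 26573114 to 40280057 in lcSSc and from 26668133 to 42547411 in dcSSc. Counts within a group differed far beyond sampling noise in all 693 pairs of libraries (smallest chi-square per degree of freedom 24.5). No library was therefore taken as a repeat of another, and each counted as 1 replicate. This check cannot tell whether 2 libraries came from the same donor.

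The first comparison set SSc monocytes against HC monocytes, since the series title ties SSc monocytes to Notch and interferon pathways. SLC1A3, which encodes a glutamate and aspartate transporter, fell in SSc, with a log2 fold change of -1.70 ± 0.31 (SE, 0.308-fold, adjusted p = 0.0203). Its level was 2.25 ± 1.46 log2 CPM (counts scaled to library size, on the log2 scale) in HC (SD, n = 15) and 1.39 ± 0.78 in SSc (SD, n = 48), means that differ by less than the fitted value, and 31 of 48 SSc libraries lay below the HC median. SLC1A3 (ENSG00000079215) lies on the plus strand of chromosome 5 from 36596588 to 36688334. The gene with the smallest p among those with higher levels, NUAK2, an AMPK-related kinase, stood at 5.75 ± 0.50 log2 CPM in SSc against 4.80 ± 0.82 in HC. Its log2 fold change was 0.84 ± 0.18 (SE), and 46 of 48 SSc libraries were above the HC median, without passing the test (adjusted p = 0.0981). SNN, which encodes the small membrane protein stannin, had 0.40 ± 0.10 and ZBTB6, a zinc finger protein gene, had 0.54 ± 0.13, each with an adjusted p of 0.128 and 41 of 48 SSc libraries above the HC median.

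By edgeR's quasi-likelihood test, 1 of 19066 genes passed the adjusted p of 0.05, and 1800 genes had an unadjusted p under 0.05, of which 1134 were higher and 666 lower. DESeq2 called 34 genes (22 higher, 12 lower) and limma voom with quality weights called 4 (3 higher, 1 lower). DESeq2 called NUAK2 (adjusted p = 0.0055), and so did limma voom (adjusted p = 0.014). Among the genes called by DESeq2, named here after their values were seen, were the interferon-induced IFIT5, IFITM1, ETV7 and APOL6 with higher levels, and the red cell genes HBA2, HBB, SLC4A1 and ALAS2 (log2 fold change 3.68, 3.42, 3.90 and 4.26, adjusted p = 0.0055, 0.0101, 0.0136 and 0.0155). LTF from the neutrophil list was also called higher by DESeq2 (log2 fold change 3.36, adjusted p = 0.00941). Lower levels called by DESeq2 included CLEC10A, a lectin of myeloid dendritic cells and some monocytes, and TSC22D3 and SAP30 from the glucocorticoid list. The SLC1A3 call ended when any 1 of 3 HC libraries was left out, with log2 fold changes of -1.65, -1.59 and -0.79 (adjusted p = 0.0544, 0.104 and 0.38), and leaving out any 1 of 6 other libraries gave 2 to 12 called genes. DESeq2 gave SLC1A3 a log2 fold change of -0.75 (adjusted p = 0.181) and limma voom -0.59, and in edgeR fits of set B1 and set B2 alone it was -0.78 (adjusted p = 0.968) and -2.36 (adjusted p = 0.055).

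**Figure D1:**
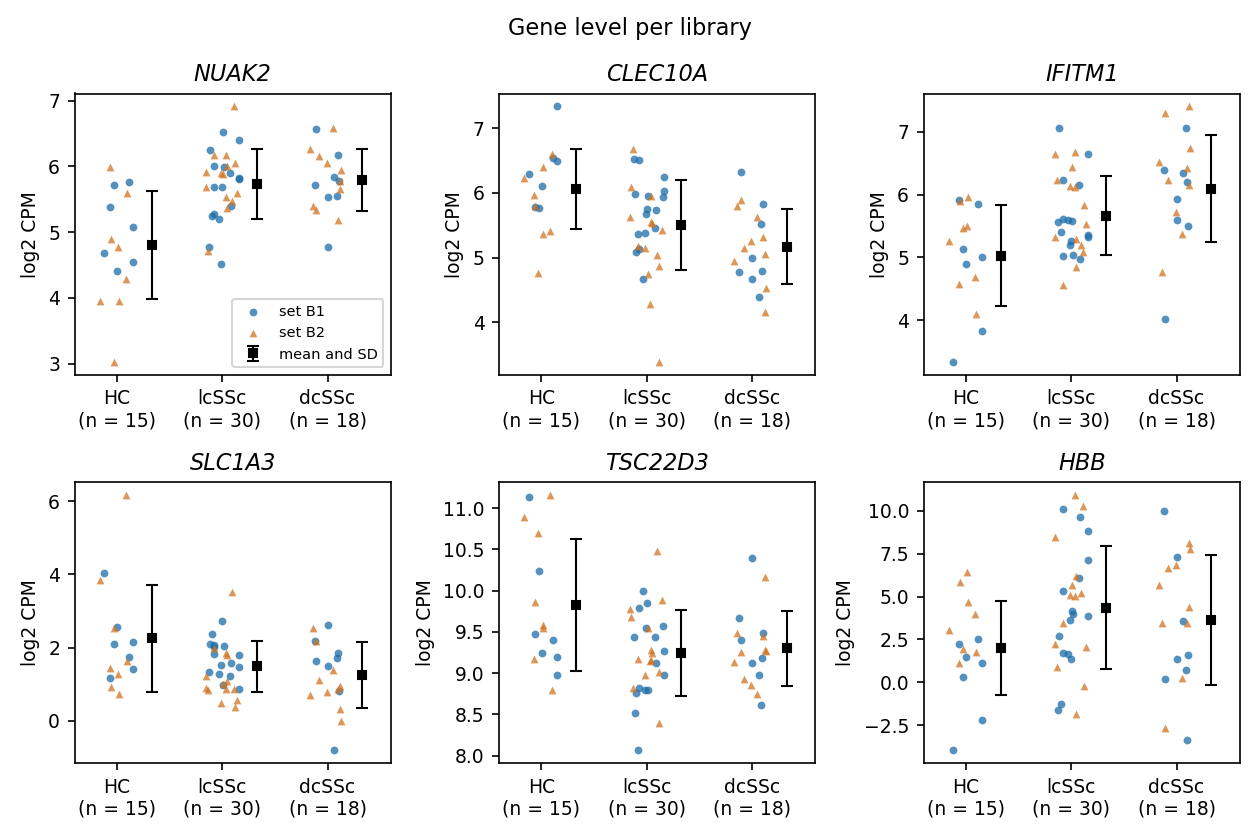
Level of 6 genes in each library as log2 CPM on the y axis, by group on the x axis, with points shaped and coloured by library set and black squares with bars giving the group mean and SD. NUAK2 lay above the HC median in 46 of 48 SSc libraries, and the mean of SLC1A3 was 2.25 in HC, with an SD of 1.46.

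Genes of the type I interferon response, the antiviral programme named in the series title, had higher levels in SSc. Of 52 genes in the list, 51 had a positive log2 fold change, with a median of 0.57, and 37 had an unadjusted p under 0.05. None was called when adjusted over all genes, and 33 were higher when adjusted over the list alone. IFIT5, an RNA-binding interferon effector, had a log2 fold change of 0.65 ± 0.17 (SE, adjusted p = 0.166) and was above the HC median in 45 of 48 SSc libraries. IFITM1, a membrane protein that restricts viral entry, had 0.85 ± 0.22 (adjusted p = 0.166), and IRF9, the DNA-binding part of the complex that drives interferon-stimulated genes, had 0.38 ± 0.12 (adjusted p = 0.276). IFI27 had 3.61 ± 0.95 (adjusted p = 0.166), with 29 of 48 SSc libraries above the HC median and a median CPM of 0.375 in HC and 0.497 in SSc. The log2 fold change of IFI27 was 0.91 with limma voom, 1.83 with DESeq2 and 2.05 with marker levels of other cell types as covariates. Camera with a preset correlation called the list higher (adjusted p = 1.77e-15), a call that was lost when the correlation between its genes was estimated (adjusted p = 0.725 with an estimated correlation).

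The mean log2 CPM of the 52 interferon genes was 5.37 ± 0.38 in HC (SD, n = 15) and 5.79 ± 0.77 in SSc (SD, n = 48), a difference of 0.41 after adjustment for set, and 35 of 48 SSc libraries lay above the HC median. A two-sided permutation test gave p = 0.0488, and the value adjusted over the 30 lists was 0.379. The difference was 0.58 in set B1 (exact permutation p = 0.0783) and 0.27 in set B2 (exact permutation p = 0.342), and 0.41 (permutation p = 0.0586) without the 4 libraries that stood apart from their set. The score was also more spread in SSc: the ratio of SDs was 1.94 (permutation p = 0.0138), with 2.06 in set B1 (exact permutation p = 0.0213) and 1.82 in set B2 (exact permutation p = 0.258). A score above the HC mean plus 2 SD was seen in 15 of 48 SSc libraries, 31.2% (95% exact interval 18.7 to 46.3%), and in 1 HC library. This share was 45.8% in set B1 (25.6 to 67.2%) and 16.7% in set B2 (4.7 to 37.4%), each against the HC libraries of that set.

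**Figure D2:**
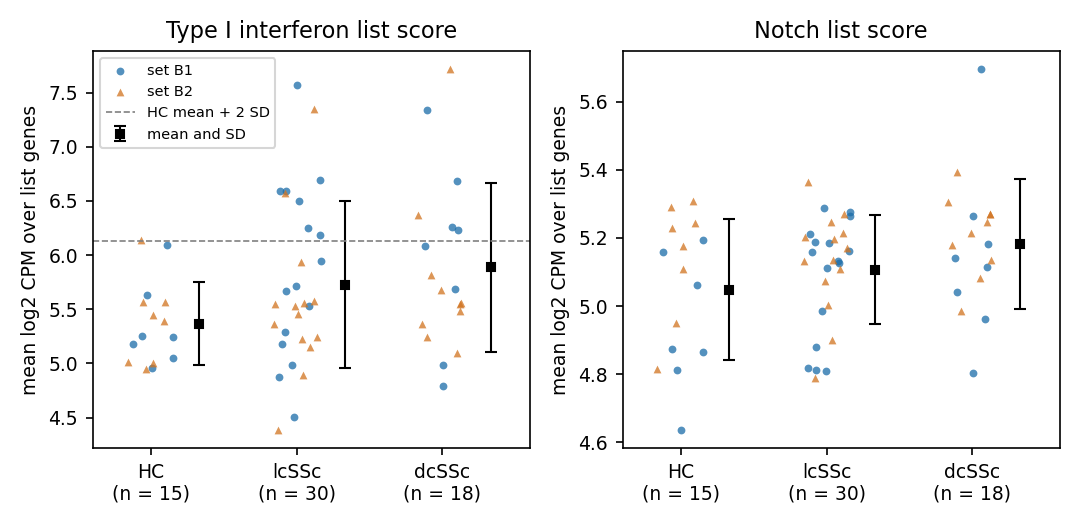
Mean log2 CPM of the type I interferon list (left) and the Notch list (right) in each library on the y axis, by group on the x axis, with points shaped and coloured by library set and black squares with bars giving the group mean and SD. The dashed line marks the HC mean plus 2 SD, which 15 of 48 SSc libraries exceeded.

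Genes of the Notch pathway, which transmits signals between neighbouring cells, had smaller median differences. Of 42 Notch genes, 27 had a positive and 15 a negative log2 fold change, with a median of 0.05, and none was called over all genes or when adjusted over the list alone. LFNG, a glycosyltransferase that modifies Notch receptors, had a log2 fold change of 0.37 ± 0.13 (SE, adjusted p = 0.333), with 42 of 48 SSc libraries above the HC median. The Notch target NRARP had 1.72 ± 0.65, the ligand DLL1 had 0.75 ± 0.30 and the ubiquitin ligase DTX4 had 0.39 ± 0.18, with adjusted p-values of 0.385, 0.4 and 0.501. Over the alternatives the log2 fold change of LFNG ranged from 0.24 to 0.47, NRARP from 0.51 to 1.83, DLL1 from 0.44 to 0.77 and DTX4 from 0.06 to 0.58, with the lowest value in set B1 for LFNG and with marker levels as covariates for the other 3. Camera did not call the list (adjusted p = 0.239). The mean log2 CPM of the list was 5.05 ± 0.21 in HC (SD, n = 15) and 5.14 ± 0.17 in SSc (SD, n = 48), with p = 0.0944 in a two-sided permutation test. The difference was 0.09 over both sets, 0.17 in set B1 (exact permutation p = 0.0687) and 0.02 in set B2 (exact permutation p = 0.732), and 0.05 (permutation p = 0.311) without the 4 libraries standing apart. Across the 48 SSc libraries, no relation between the interferon and Notch scores was detected (Pearson r = -0.007, permutation p = 0.964; Spearman rho = -0.045, permutation p = 0.763). Pearson r was 0.02 without the 2 libraries farthest from the median interferon score. It was 0.183 in set B1 (permutation p = 0.395; rho = 0.123) and -0.235 in set B2 (permutation p = 0.263; rho = -0.086).

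Camera with a preset correlation of 0.01 called 11 of the 30 lists between SSc and HC, 6 higher and 5 lower, and with an estimated correlation it called 0 (smallest adjusted p = 0.619). Fry called 0 lists as well (smallest adjusted p = 0.294). Besides type I interferon, the lists called higher were interferon gamma response, NF-kB inflammatory mediators, platelet markers, red cell markers and cell cycle. Their adjusted p-values with the preset correlation were 0.00339, 0.0183, 0.000905, 0.025 and 0.025. With an estimated correlation, each of these 5 lists had an adjusted p of 0.725. The lists called lower were glucocorticoid response, alternatively activated macrophage markers, MHC class II presentation, cytosolic ribosomal proteins and nuclear respiratory chain genes. Their adjusted p-values with the preset correlation were 1.46e-05, 0.00275, 0.00428, 1.73e-08 and 0.00901. With an estimated correlation they were 0.619 for the glucocorticoid and alternatively activated lists, 0.725 for MHC class II and ribosomal proteins, and 0.739 for the respiratory chain.

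In the interferon gamma list, 29 of 36 genes had a positive log2 fold change, with 1 higher when adjusted over the list alone and 0 over all genes. In the NF-kB list, 28 of 32 genes were positive, and in the cell cycle list 15 of 20, with 0 called over all genes or when adjusted over the list alone. The glucocorticoid response list, genes induced by steroid hormones, had 16 of 19 genes negative with a median log2 fold change of -0.44, with 0 called over all genes and 7 lower when adjusted over the list alone. These included SAP30, part of a histone deacetylase complex (-1.21 ± 0.30 SE, adjusted p = 0.129), TSC22D3, the glucocorticoid-induced leucine zipper (-0.68 ± 0.17, adjusted p = 0.129), and the co-chaperone FKBP5 (-0.82 ± 0.26, adjusted p = 0.276). The score of this list was below the HC median in 39 of 48 SSc libraries, with a difference of -0.31 (permutation p = 0.0554). That difference was -0.04 in set B1 (exact permutation p = 0.886) and -0.55 in set B2 (exact permutation p = 0.012). The alternatively activated macrophage list had 5 genes lower and 1 higher when adjusted over the list alone, 0 over all genes. The mannose receptor MRC1 had a log2 fold change of -0.77 ± 0.25 (adjusted p = 0.302) and the transglutaminase TGM2 had 1.25 ± 0.50 (adjusted p = 0.406). In MHC class II presentation, 8 of 12 genes were negative, with 1 lower when adjusted over the list alone and 0 over all genes. Median log2 fold changes were -0.07 over 83 ribosomal protein genes and -0.04 over 90 nuclear respiratory chain genes, with 0 genes called over all genes or when adjusted over the list alone.

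**Figure D3:**
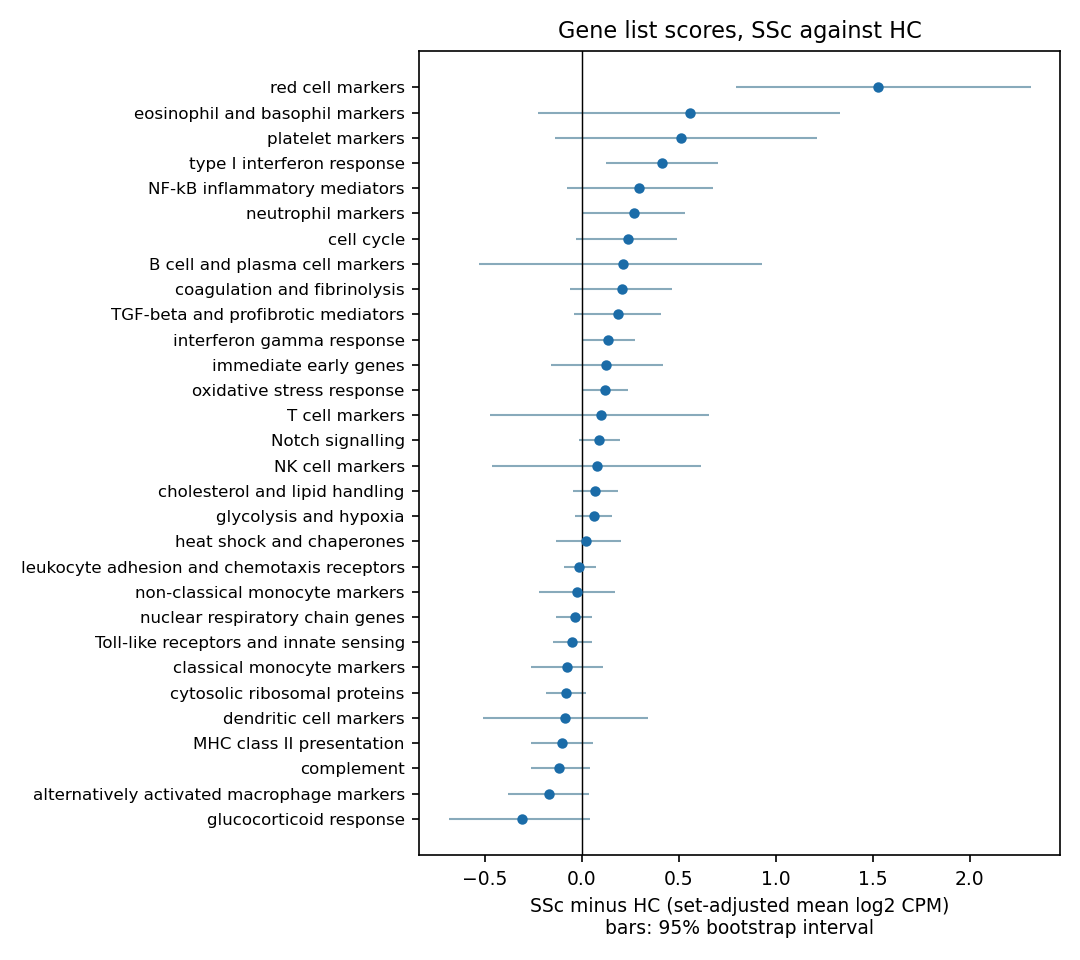
Difference of mean list score between SSc and HC on the x axis (set-adjusted mean log2 CPM) for each of the 30 gene lists on the y axis, with bars for the 95% bootstrap interval. Red cell markers had the highest difference (1.53) and the glucocorticoid response list the lowest (-0.31).

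Markers of other blood cells were present at varying levels. Red cell transcripts were higher in SSc: all 6 genes in the list had a positive log2 fold change, with 5 higher when adjusted over the list alone and 0 over all genes. The beta-globin gene HBB had a log2 fold change of 3.76 ± 1.13 (SE, adjusted p = 0.265). Its mean log2 CPM was 2.01 ± 2.73 in HC (SD, n = 15) and 4.09 ± 3.64 in SSc (SD, n = 48), means that differ by less than the fitted value. The red cell score differed by 1.53 (permutation p = 0.0152, 0.379 over the 30 lists), by 2.26 in set B1 (exact permutation p = 0.0214) and by 0.86 in set B2 (exact permutation p = 0.288). With marker levels of 6 other cell types as covariates, which include the red cell list itself, the log2 fold change of HBB was -0.11, and it was 1.38 with limma voom, 2.51 without the 4 libraries standing apart and 6.07 in set B1. In the platelet list, all 20 genes were positive, with 0 called when adjusted over the list alone, NRGN at 0.18 ± 0.16 and TUBB1 at 0.36 ± 0.39. Log2 fold changes were 0.05 ± 0.31 for IL7R and 0.27 ± 0.32 for TCF7 (T cells), 0.29 ± 0.39 for MS4A1 and 0.01 ± 0.18 for CD79B (B cells), and 0.18 ± 0.40 for GNLY and 0.53 ± 0.37 for PRF1 (NK cells). They were 0.43 ± 0.24 for FFAR2 and -0.03 ± 0.25 for PROK2 (neutrophils), and 0.65 ± 0.42 for GATA2 (basophils). The smallest unadjusted p among these 9 genes was 0.0735. Log2 fold changes ranged over the alternatives from 0.12 to 0.86 for PRF1, -0.15 to 0.66 for TCF7, -0.06 to 0.62 for MS4A1, -0.20 to 0.58 for GNLY, -0.04 to 1.02 for FFAR2, -0.20 to 0.72 for GATA2 and -0.02 to 0.84 for TUBB1. In the dendritic cell list, CLEC10A was at -0.71 ± 0.17 (adjusted p = 0.128) and TCF4 at 0.15 ± 0.13, and 3 of 11 genes were lower when adjusted over the list alone, 0 over all genes.

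Besides Notch, camera did not call 18 lists. Their score differences were 0.56 for eosinophil and basophil markers, 0.27 for neutrophil markers, 0.21 for B cell markers, 0.10 for T cell markers, 0.08 for NK cell markers and -0.09 for dendritic cell markers. They were 0.21 for coagulation and fibrinolysis, 0.19 for profibrotic mediators, 0.13 for immediate early genes, 0.12 for oxidative stress, 0.07 for cholesterol and lipid handling, 0.06 for glycolysis and hypoxia and 0.02 for heat shock. Classical and non-classical monocyte markers differed by -0.08 and -0.02, complement by -0.12, Toll-like receptors by -0.05 and adhesion and chemotaxis receptors by -0.01. Unadjusted permutation p-values of these 18 lists ranged from 0.081 to 0.898. Adjusted over the list alone, 4 genes of the profibrotic list and 2 of the coagulation list were higher and 1 of the classical monocyte list was lower, with 0 over all genes. Apart from these and the dendritic cell list, the 18 lists had 0 called genes either way in the edgeR fit. DESeq2 called LTF of the neutrophil list higher in SSc (log2 fold change 3.36, adjusted p = 0.00941). Sign differed between the median (0.03) and the mean (-0.02) of the complement genes, and between the median (-0.01) and the mean (0.02) of the non-classical monocyte genes.

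The second comparison asked whether limited disease alone differed from HC. NUAK2 again had the smallest p among higher genes, with a log2 fold change of 0.82 ± 0.19 (SE, adjusted p = 0.218), next to the alpha-globin gene HBA2 (4.50 ± 1.10) and the cohesin subunit SMC3 (0.27 ± 0.07), both with the same adjusted p. Among lower genes, FCGBP, an Fc-binding mucin-like protein, had -1.46 ± 0.30 (adjusted p = 0.167), SLC1A3 had -1.60 ± 0.34 (adjusted p = 0.167), and AFMID, an enzyme of tryptophan breakdown, had -0.49 ± 0.12 (adjusted p = 0.218). EdgeR called 0 of 19066 genes, with 1738 at an unadjusted p under 0.05, while DESeq2 called 17 (14 higher, 3 lower), with HBA2 among them (adjusted p = 1.6e-05), and limma voom 0. The log2 fold change of HBA2 was 1.51 with limma voom, 2.5 without the 4 libraries standing apart and 0.17 with marker levels as covariates, and that of SLC1A3 was -0.48 with limma voom, -0.66 with DESeq2, -0.73 in set B1 and -2.23 in set B2. Without the 4 libraries standing apart, edgeR called FCGBP lower (log2 fold change -1.48, adjusted p = 0.0377).

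In the interferon list, 50 of 52 genes were positive in lcSSc with a median log2 fold change of 0.48, with 0 genes called over all genes and 1 higher when adjusted over the list alone. Values were 0.68 ± 0.18 for IFIT5, 2.98 ± 0.95 for IFI27, 1.48 ± 0.52 for IFI44L and 1.0 ± 0.36 for IFI44 (adjusted p from 0.266 to 0.407). With limma voom IFI27, IFI44L and IFI44 were at 0.86, 0.63 and 0.49, with marker levels at 1.51, 0.79 and 0.53, and IFI27 was at 1.98 with DESeq2. The interferon score differed by 0.35 (permutation p = 0.107). In the Notch list, LFNG had 0.33 ± 0.13, DTX4 0.46 ± 0.19, NOTCH1 0.34 ± 0.15 and its nuclear partner RBPJ 0.34 ± 0.15 (adjusted p from 0.445 to 0.486), with 0 called over all genes or when adjusted over the list alone, and the score differed by 0.07 (permutation p = 0.241). NOTCH1, RBPJ and DTX4 were at 0.11, 0.12 and 0.22 without the 4 libraries standing apart. These 3 and LFNG were at 0.07, 0.10, 0.07 and 0.19 with marker levels as covariates, at 0.05, 0.07, 0.11 and 0.17 in set B1, and at 0.62, 0.58, 0.79 and 0.48 in set B2. Camera called 11 lists, 7 higher and 4 lower. The higher ones were type I interferon, interferon gamma, NF-kB, platelet, red cell, eosinophil and basophil, and profibrotic lists, and the lower ones were glucocorticoid, alternatively activated, ribosomal and respiratory chain lists. With an estimated correlation camera called 0 of them (smallest adjusted p = 0.686 with an estimated correlation), and fry also called 0.

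The third comparison set diffuse disease against HC. IFITM1 had a log2 fold change of 1.08 ± 0.25 (SE), the 3' end processing factor CSTF2T 0.43 ± 0.10 and the interferon-induced APOL6 0.54 ± 0.13, each with an adjusted p of 0.141. SLC1A3 had -1.79 ± 0.39 and the serotonin receptor gene HTR7 -0.72 ± 0.17, both with an adjusted p of 0.141, and CLEC10A had -0.87 ± 0.21 (adjusted p = 0.143). SLC1A3 was at -0.70 with limma voom, -0.83 with DESeq2, -0.82 in set B1 and -2.49 in set B2, and CSTF2T was at 0.13 in set B1 and 0.66 in set B2. EdgeR called 0 of 19066 genes, with 1591 at an unadjusted p under 0.05, while DESeq2 called 14 (7 higher, 7 lower) and limma voom 9 (8 higher, 1 lower). The lower gene in the limma voom fit was CLEC10A (log2 fold change -0.98, adjusted p = 0.00816). DESeq2 gave it an adjusted p of 0.0386.

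All 52 interferon genes were positive in dcSSc, with a median log2 fold change of 0.63. None was called over all genes and 36 were higher when adjusted over the list alone. IFI27 had 4.25 ± 1.04, IRF9 0.46 ± 0.14 and IFIT5 0.62 ± 0.19 (adjusted p from 0.158 to 0.332), with IFI27 at 0.96 with limma voom, 1.68 with DESeq2, 2.58 with marker levels and 2.66 in set B1. The interferon score differed by 0.52 (permutation p = 0.0243, 0.423 over the 30 lists). In the Notch list, DLL1 had 1.18 ± 0.34 (adjusted p = 0.3), NRARP 2.08 ± 0.73, LFNG 0.41 ± 0.14 and the Notch target HES4 0.80 ± 0.33 (adjusted p from 0.398 to 0.51). HES4, which was also in the non-classical monocyte list, was at 1.59 in set B1 and 0.27 in set B2. NRARP was at 0.89 with marker levels as covariates. None of the 42 Notch genes was called over all genes and 1 was higher when adjusted over the list alone, and the Notch score differed by 0.13 (permutation p = 0.0571). Camera called 11 lists, 5 higher and 6 lower. The higher ones were type I interferon, interferon gamma, B cell, platelet and cell cycle lists, and the lower ones were glucocorticoid, alternatively activated, MHC class II, classical monocyte, ribosomal and respiratory chain lists. With an estimated correlation camera called 0 (smallest adjusted p = 0.378 with an estimated correlation), and fry called 0.

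The last comparison set the subtypes against each other. DHRS1, a dehydrogenase of the short-chain family, was at 4.65 log2 CPM in dcSSc and 4.27 in lcSSc, with a log2 fold change of 0.40 ± 0.08 (SE, n = 18 and 30) that missed the threshold (adjusted p = 0.06). It was called by DESeq2 (adjusted p = 0.0138), by limma voom (adjusted p = 0.00696) and by edgeR without the 4 libraries standing apart (adjusted p = 0.0187). The vitamin transporter SLC5A6 had 0.48 ± 0.12 and ZNF10 0.60 ± 0.18, while the actin-binding PALLD had -1.05 ± 0.27, and the transcription factors ZEB2 and PLAGL1 had -0.38 ± 0.10 and -0.36 ± 0.10 (adjusted p from 0.842 to 0.996). PALLD was at -0.41 without the 4 libraries standing apart, -0.40 with limma voom, -0.59 with DESeq2, -0.50 with marker levels, -0.49 in set B1 and -1.59 in set B2. SLC5A6, ZNF10 and DHRS1 were at 0.20, 0.31 and 0.25 in set B1, and ZEB2 at -0.23 without the 4 libraries standing apart. EdgeR called 0 of 19066 genes, with 792 at an unadjusted p under 0.05, while DESeq2 called 3 (2 higher, 1 lower) and limma voom 1.

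Among interferon genes in dcSSc against lcSSc, 49 of 52 were positive with a median log2 fold change of 0.15, with 0 called over all genes or when adjusted over the list alone. Values were 0.47 ± 0.21 for IFITM1, 0.32 ± 0.16 for ISG20, 1.28 ± 0.84 for IFI27 and 0.17 ± 0.12 for the tetherin gene BST2, each with an adjusted p of 0.996. Over the alternatives IFI27 ranged from -0.91 in set B1 to 2.73 in set B2, with -0.30 by DESeq2, IFITM1 from 0.31 to 0.59, ISG20 from 0.21 to 0.41 and BST2 from 0.03 to 0.22. The score differed by 0.18 (permutation p = 0.433), and a score above the HC mean plus 2 SD was seen in 9 of 30 lcSSc libraries (30%, exact interval 14.7 to 49.4%) and 6 of 18 dcSSc libraries (33.3%, exact interval 13.3 to 59.0%). In the Notch list, DLL1 had 0.86 ± 0.28, NUMBL 0.27 ± 0.10, HES4 0.62 ± 0.27 and HES1 1.5 ± 0.66, each with an adjusted p of 0.996. HES4 was in the non-classical monocyte list as well. HES1 ranged over the alternatives from -0.83 without the 4 libraries standing apart to 2.67 in set B1, with -0.32 by DESeq2, NUMBL from 0.11 to 0.39 and HES4 from 0.40 to 0.77. None of the 42 was called over all genes or when adjusted over the list alone. Camera called 12 lists, 6 higher and 6 lower in dcSSc. Higher were type I interferon, heat shock, non-classical monocyte, T cell, B cell and NK cell lists, and lower were immediate early, MHC class II, classical monocyte, coagulation, oxidative stress and ribosomal lists. The mean log2 fold change of the heat shock list was -0.04 and its median 0.01, although camera called it higher. With an estimated correlation camera called 0 (smallest adjusted p = 0.712 with an estimated correlation), and fry called 0.

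The effect of SSc was also compared between set B1 and set B2. EdgeR's interaction test called 0 of 19066 genes, with 655 at an unadjusted p under 0.05, and DESeq2 (730 at an unadjusted p under 0.05) and limma voom called 0 as well.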

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

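Chosen only after the results were seen were the tests over other splits of the libraries, the monocyte share test and the test of group medians. So was the bootstrap interval of the interferon difference without the libraries standing apart, while the permutation test without them was planned. Between dcSSc and lcSSc, camera with a preset correlation called 12 gene lists, while camera with an estimated correlation and fry called 0.

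Group labels were permuted within set to ask whether chance could give counts as large, over 50 splits with the real one included. For the lists called by camera with a preset correlation, chance cannot be excluded in any of the 4 comparisons. Between SSc and HC, 16 splits gave at least the real count of 11 lists, and the highest other count was 15, with a median of 9. Between lcSSc and HC, 16 splits gave at least 11, and the highest other count was 17. Between dcSSc and HC, 22 splits gave at least 11, and the highest other count was 19. Between dcSSc and lcSSc, 19 splits gave at least 12, and the highest other count was 21, with a median of 11. For genes between SSc and HC, 18 of the 50 splits gave at least the 1 gene called, so chance cannot be excluded, and the highest other count was 1659. The counts of 0 genes for lcSSc against HC, dcSSc against HC, dcSSc against lcSSc and the set interaction cannot be tested in this way, since any of the 50 splits gives at least 0. Their highest other counts were 1280, 447, 128 and 35. The median count of genes over the other splits was 0, but those that called several times more genes than the real one point to a structure of the libraries, the source of which was not tested.

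The type I interferon score was higher in SSc by 0.41 (95% bootstrap interval 0.13 to 0.70), while its permutation p was 0.379 when adjusted over the 30 lists. Without the 4 libraries standing apart the difference was 0.41 (0.12 to 0.69), although the permutation p moved to 0.0586. It was 0.35 (0.05 to 0.66) with the 6 marker levels of other cell types as covariates, and 0.42 (0.14 to 0.71) with total count as a covariate. These values argue against each of these as the whole source of the difference, although the differences with covariates had bootstrap intervals only and no permutation test. Chance stays open, given the permutation p-values above, as do disease itself and donor differences such as age, which was not used here.

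The red cell score was higher in SSc by 1.53 (permutation p = 0.0152, 0.379 over the 30 lists), with 0.86 in set B2 (exact permutation p = 0.288). The 5 transcripts with an unadjusted p under 0.05 moved together over the SSc libraries, with a median pairwise Spearman rho of 0.86. The smallest rho of any pair was 0.539 and the largest 0.946. This is consistent with red cells, or their RNA, carried into some preparations as a candidate source, although selection on CD14 should remove most of them. A lower share of monocytes would raise markers of other cell types as well. The T cell score differed by 0.10 (unadjusted permutation p = 0.756, bootstrap interval -0.474 to 0.657) and the NK cell score by 0.08. Differences were 0.56 for eosinophil and basophil, 0.51 for platelet, 0.27 for neutrophil and 0.21 for B cell markers. Dendritic cell markers went the other way (-0.09). The red cell score less the T cell score differed by 1.47 (unadjusted permutation p = 0.0319). The red cell difference was larger than that of any other cell type listed. However, its contrast with the T cell score was chosen after the results were seen and rests mostly on the red cell difference. The contrast therefore cannot tell whether a lower share of monocytes was the whole source. Chance stays open for the red cell difference itself. Whether more red cell RNA in the blood of people with SSc contributed was not tested.

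The glucocorticoid response score was lower in SSc by a difference of -0.31 (95% bootstrap interval -0.69 to 0.04) (-0.04 in set B1 and -0.55 in set B2). The difference of group medians was -0.2 (permutation p = 0.129), and without the libraries standing apart the difference was -0.24 (-0.63 to 0.11). The difference of medians kept its direction but missed the threshold, so a few HC libraries with high levels cannot be told apart from a shift of the whole group. The SD of the score was 0.77 in HC and 0.45 in SSc. The HC libraries highest in SLC1A3, at 6.18, 4.05 and 3.86 log2 CPM, were also the highest HC libraries in TSC22D3, at 11.16, 11.13 and 10.89. This overlap was seen only after the values were known. The SLC1A3 call and the lower glucocorticoid score may thus rest partly on the same HC libraries. Steroid treatment, time of day and stress at sampling were not tested.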

How the results depend on the processing

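Leaving out each library in turn was chosen only after the result was seen; the other alternatives were planned. Where a value moved, the cause was not tested, except that single sets have fewer libraries. Of 639 values of named genes under the alternatives, 581 kept their direction and their side of the threshold, 26 passed it, 6 no longer did, all for SLC1A3, and 26 changed sign. Only 1 of the 68 gene results behind these values, SLC1A3 between SSc and HC, was called in the main fit. For the others, keeping the side meant staying uncalled, whatever the change in size, so the tally does not measure how stable the values were.

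The SSc against HC count of 1 gene became 34 with DESeq2, 4 with limma voom, 7 without the set covariate, 4 in set B2, and 0 without the libraries standing apart or with marker levels as covariates. It ranged from 0 to 12 when each library was left out. Set B1 alone also called 1 gene, but this was CTTNBP2 (log2 fold change -2.515, adjusted p = 0.000139), named after its values were seen. Set B2 alone did not call CTTNBP2, and neither set alone called SLC1A3. DESeq2 over both sets called CTTNBP2 lower too (adjusted p = 0.00941). The lcSSc against HC count of 0 became 17 with DESeq2 and 1 without the libraries standing apart. The dcSSc against HC count of 0 became 14 with DESeq2, 9 with limma voom and 1 in set B1. The dcSSc against lcSSc count of 0 became 3 with DESeq2 and 1 with limma voom, without the libraries standing apart or without the set covariate.

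All 4 counts of lists became 0 with an estimated correlation and 0 with fry. The 11 lists of SSc against HC (6 higher, 5 lower) became 6 with marker levels (2 higher, 4 lower), 17 in set B1 (15 higher, 2 lower) and 5 in set B2 (1 higher, 4 lower). The 11 lists of lcSSc against HC (7 higher, 4 lower) became 6 with marker levels (2 higher, 4 lower), 16 in set B1 (14 higher, 2 lower) and 3 in set B2 (0 higher, 3 lower). The 11 lists of dcSSc against HC (5 higher, 6 lower) became 15 in set B1 (13 higher, 2 lower) and 8 in set B2 (3 higher, 5 lower), and the 12 lists of dcSSc against lcSSc became 7 without the libraries standing apart (3 higher, 4 lower).

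The interferon score difference did not pass in set B1 (0.579), in set B2 (0.266) or without the libraries standing apart (0.406), nor did its SD ratio in set B2 (1.821). The share of SSc libraries above the HC range was 16.7% in set B2. The correlation of interferon and Notch scores, -0.007, was 0.216 with z values, 0.183 in set B1 and 0.004 without the libraries standing apart.

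Signs between SSc and HC changed for these genes. With marker levels, which include these genes, IL7R was at -0.21, CD79B at -0.06, GNLY at -0.09, NRGN at -0.04, TUBB1 at -0.02 and HBB at -0.11 (from 3.76). GATA2 moved to -0.20 (from 0.65) and HDC to -0.40 (from 0.64), although their eosinophil and basophil list is not among the marker levels. With limma voom IL7R was at -0.08 and PROK2 at 0.09. Without the libraries standing apart IL7R was at -0.03, CD79B at -0.01 and PROK2 at 0.05. In set B1 TCF7 was at -0.15 and MS4A1 at -0.06. In set B2 CD79B was at -0.06, GNLY at -0.20, FFAR2 at -0.04 (from 0.43), PROK2 at 0.02 and TUBB1 at -0.02. With the subtypes as 1 group CD79B was at -0.01. Between dcSSc and lcSSc, IFI27 was at -0.30 with DESeq2 and -0.91 in set B1, and HES1 at -0.32 with DESeq2, -0.83 without the libraries standing apart and -0.70 in set B2.

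Depth limits only the least abundant genes, since totals were at least 26573114.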

Other observations

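The genes in this part were chosen only after their values were seen. In the dendritic cell list, the IgE receptor gene FCER1A had a log2 fold change of -0.85 ± 0.25 (SE, adjusted p = 0.249) and the CD1 family gene CD1E had -0.85 ± 0.26 (adjusted p = 0.276). Both were lower when adjusted over the list alone, while XCR1, a marker of another dendritic cell type, had 0.60 ± 0.45. Of the 11 genes in that list 5 were positive, and camera did not call it (adjusted p = 0.115). In the profibrotic list, the TGF-beta feedback inhibitor SMAD7 had 1.05 ± 0.36 (adjusted p = 0.339), SKIL 0.91 ± 0.33 (adjusted p = 0.36) and the receptor gene TGFBR1 0.26 ± 0.09 (adjusted p = 0.332). These 3 genes were higher when adjusted over the list alone, and 0 genes of either list were called over all genes.

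Variation between libraries had other main axes than group. Over 9468 genes, the first component held 26.4% of the variance and had AREG, THBS1, RGS1 and HBB as its leading genes. Group accounted for 3.1% and set for 11.1% of its scores. The second component held 20.7% and had FCRL1, THEMIS, FCRL6 and GZMA as its leading genes, with 2.5% by group. The fifth held 4.6%, had IFI44L, SIGLEC1 and IFI44 as its leading genes, and had 3.1% by group. None of these shares by group or set was tested against chance, and a small share can arise without any relation.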
